A study of Mus musculus with 209 samples.

How the data were processed

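RNA from liver, quadriceps muscle, perigonadal fat and ascending aorta of male Ldlr-/-.Leiden mice was sequenced from 67 animals in 65, 67, 42 and 35 libraries, 1 per animal and tissue. Per the labels' protocols, libraries were made from poly(A) RNA with a directional kit and sequenced as read pairs. The deposited files hold raw counts of read pairs per gene, made by the authors, 1 library per file. The submitters' processing notes name Trimmomatic, STAR 2.5, HTSeq 0.6.1p1, DESeq2 and the build GRCm38 without stating settings or an annotation. The counts are whole numbers in 54446 genes, and 5 summary lines of HTSeq were left out. Read pairs without a gene were 1.67 to 8.27% of the total (median 2.52%), ambiguous ones 2.22 to 5.84% (median 3.82%) and pairs aligned to several places 2.97 to 12.91% (median 6.03%), which HTSeq does not count. Genes of families with near-identical copies are therefore uncertain.

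Gene identifiers were matched to GENCODE vM21 on GRCm38, 53229 with their version, 1180 without it and 37 not at all. Coordinates are 1-based. Groups came from the labels: chow, HFD control, semaglutide, running wheel, and both treatments. A reference group killed at the start of treatment, which the labels mention, is not among these libraries. The labels give no sequencing batch or cage.

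Depth was 7717769 to 34219064 counted read pairs per library. On simulated groups drawn from these libraries' own spread, the combined treatment's comparison recovered 76.1%, 86.6% and 95.5% of genes changed 1.5-, 2- and 4-fold in liver, 68.7%, 86.6% and 98.5% in muscle, 44.8%, 67.2% and 92.4% in pgWAT, and 49.3%, 82.1% and 87.9% in aorta. The diet comparison in aorta, with 4 chow animals, recovered 28.4%, 65.7% and 83.3%.

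Each tissue was fitted apart with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr with the groups, libraries were scaled by TMM, and all 5 groups entered 1 quasi-likelihood fit with robust dispersions. The 7 comparisons were HFD control against chow, each treatment against HFD control, the combined treatment against each single one, and the interaction (combined minus semaglutide, minus running minus HFD control). P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Tests were 2-sided, except that the permutation test of clock genes in a pair of tissues asked only for changes in the same direction.

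Gene lists were written before the data were examined, as were the comparisons, the tests and the rule for naming genes. List members are counted as called over all genes and with p-values adjusted over the list alone. Lists of 3 or more measured members were tested with camera (limma 3.58.1, voom values) at a preset inter-gene correlation of 0.01, adjusted over the lists of a tissue and comparison, and again with the correlation estimated per list and with fry. Camera asks whether a list moves more than other genes, and fry whether its genes move, on balance, 1 way. On simulated data, 51 lists were tested in each tissue, 1 raised and the others unchanged, and 0 unchanged lists were called. The simulated genes were drawn independently, so this does not test camera on correlated genes.

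Genes named in the text are the 4 largest rises and 4 largest falls among called genes of a comparison with a mean of at least 5 CPM in the higher group and an assigned name, up to 4 members per list with the smallest adjusted p, and Glp1r, Ldlr, Gcgr, Gipr, Fgf21, Gdf15, Lep, Adipoq, Il6, Mstn, Fndc5 and Cd36. Tph2, Itgad, Crtac1, Srpx2, Lipf, Slc5a7 and 1700047G03Rik were chosen after their values were seen, and so were the liver genes of other tissues given per animal. CPM of Ldlr, of liver genes of other tissues given per animal and of Ndufa12 in a single library are scaled to the library total, and other CPM of genes to the total corrected by TMM. No fold change is given against a group with 3 or fewer counts. For named genes that were called, and for Gpx5 in pgWAT, the ratio of group means was recomputed without each library in turn. Where the ratio of a called gene, or of Gpx5, moved by over 1.5 times, the fit was repeated without that library.

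The liver RNA share of a library is the summed CPM of 11 hepatocyte secretory genes divided by their mean sum in liver libraries, in percent. A gene counts as one that liver RNA could set when the highest group's mean share of its liver level reaches 5% of its lowest group mean, which holds for 760 of 14510 genes in muscle, 3379 of 18577 in pgWAT and 518 of 18869 in aorta. Epithelial duct content of pgWAT was scored as the mean log2 CPM of marker genes written after the values were seen, with libraries above 3 left out in 1 alternative. Library pairs were compared by a mean chi-square per gene over genes with at least 20 counts in both together.

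The share of diet-changed genes moved the opposite way by a treatment used 2 random equal parts of the HFD controls, 1 for each effect, over 10 splits, and splits with fewer than 20 diet-called genes were left out. Simulated true ratios of 0.5 gave 0.412 to 0.419, so the ratios run low. Correlations between tissues used list means with group means removed and 1e+05 permutations within groups, over 36 relations. Differences of an effect between tissues were tested by permuting treatment labels of animals jointly over both tissues, for genes called in opposite directions.

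Alternatives set before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, a fit of only the groups compared, adipocyte scores (muscle, aorta) or epididymis scores (pgWAT) as covariates, aorta without the 2 samples from which excess fat was removed, aorta without each chow animal, and unsplit controls. Alternatives chosen after the data were seen were leaving out genes that liver RNA could set, the liver RNA share, the duct score or the mean level of Ndufa12 and Gpx1 as covariates, and leaving out or merging single libraries. No library was left out of the reported values.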

Results

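RNA was sequenced in 65 liver, 67 muscle, 42 fat and 35 aorta libraries from 67 male mice of the Ldlr-/-.Leiden strain, which lacks a working LDL receptor and becomes obese, with fatty liver and atherosclerosis, on a high-fat diet. Mice stayed on chow, or ate a lard-based high-fat diet (HFD) for 20 weeks and then for 14 more weeks as controls or with a treatment. The treatments were daily semaglutide (0.12 mg/kg), an agonist of the GLP-1 receptor, a running wheel in the cage, or both together. Liver had 8 chow, 14 HFD control, 14 semaglutide, 15 running and 14 combined-treatment animals. Quadriceps muscle had 8, 15, 15, 15 and 14 in the same order, perigonadal white adipose tissue (pgWAT) had 7, 10, 7, 10 and 8, and ascending aorta had 4, 7, 8, 9 and 7. All 4 tissues were available from 21 animals. Read pairs counted in genes per library ranged from 12715283 to 19560219 in liver, 7717769 to 34219064 in muscle, 13229805 to 20902238 in pgWAT and 13886882 to 22698972 in aorta. Each change below is a log2 fold change ± its standard error, and p-values are adjusted over all genes tested unless stated otherwise. Gene lists have camera p-values adjusted over the lists, first at a preset and then at an estimated correlation between genes.

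Every animal carries the Ldlr knockout, so Ldlr reads do not serve to check the groups, and gene-level counts cannot show the altered part of the gene. Ldlr was counted in every library, at 314 to 641 CPM (counts scaled to the library total) in liver, 3.14 to 14.1 in muscle, 63.7 to 244 in pgWAT and 17.5 to 69.2 in aorta. In liver it was lower under the combined treatment than in HFD controls (-0.20 ± 0.07, adjusted p = 0.0245). Glp1r, which encodes the receptor semaglutide acts on, passed the expression filter in aorta alone, at a mean of 0.21 CPM (SD 0.261, n = 7) in HFD controls, and did not differ there between combined treatment and control (-0.35 ± 0.98, adjusted p = 0.931). The labels describe group housing and name no cages, so the tests treat animals as independent although a wheel is shared by a cage.

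**Figure D1:**
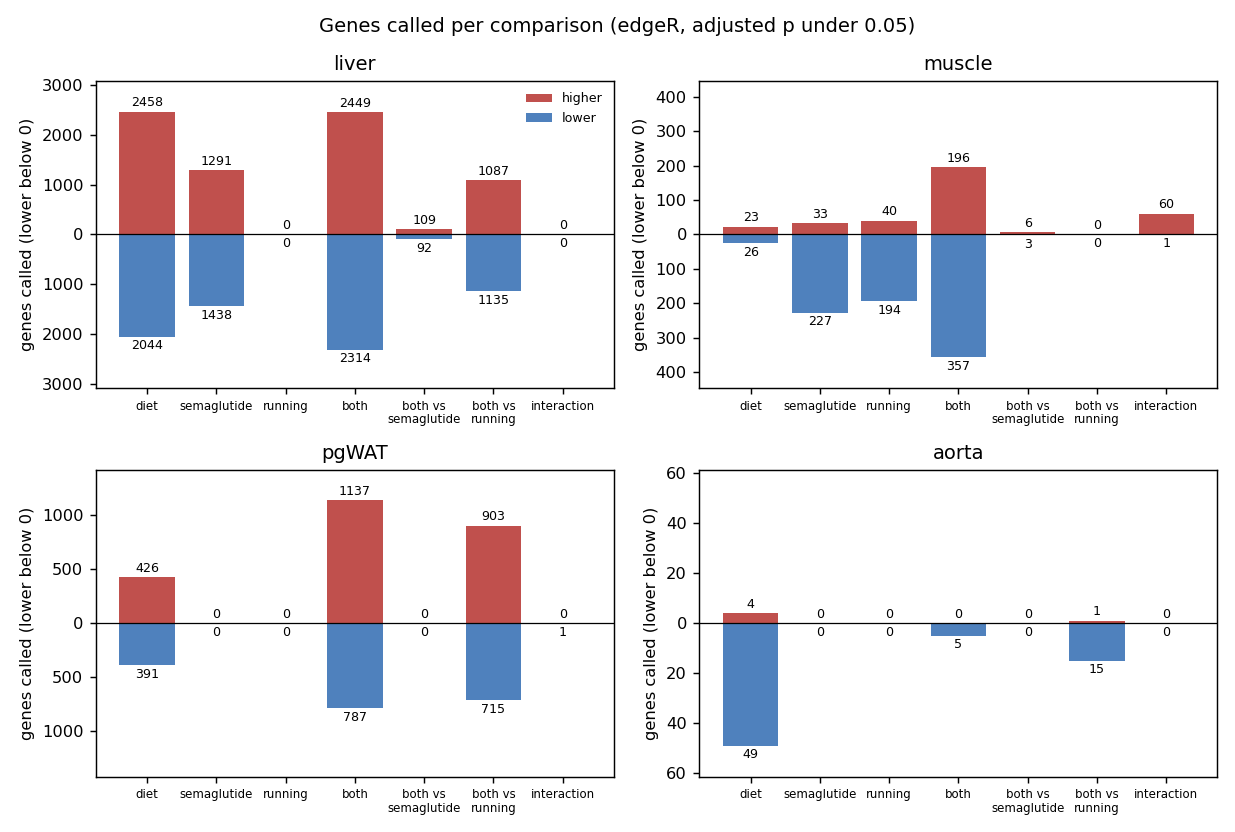
Genes called in each comparison, 1 panel per tissue: bars above 0 count genes higher in the first-named group and bars below 0 genes lower in it (edgeR, adjusted p under 0.05). In liver the tallest bars are 2458 higher genes for the diet and 2314 lower for the combined treatment, and the running bar is at 0 in liver, pgWAT and aorta.

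In liver, the diet comparison asked how 14 HFD controls differed from 8 chow-fed mice, and 4502 of 15142 genes passed (2458 higher, 2044 lower). Macrophage markers were higher in HFD livers: 22 of 22 members rose (22 adjusted over the list alone), for example Cd68 (1.36 ± 0.17) and the complement gene C1qb (1.18 ± 0.17; camera adjusted p = 3.47e-19 preset, 0.169 estimated). Of genes that mark lipid-laden macrophages, 11 of 15 members rose (11 adjusted over the list alone). Among them, Trem2, a lipid-sensing receptor, was 6.58-fold the chow level (2.72 ± 0.39, adjusted p = 2.13e-07, ENSMUSG00000023992.14, chromosome 17, 48346401 to 48354147), and Gpnmb rose 10.1-fold (3.34 ± 0.56, adjusted p = 5.7e-06, ENSMUSG00000029816.10, chromosome 6, 49036546 to 49070929; list camera adjusted p = 5.11e-07 preset, 0.237 estimated). Of extracellular matrix genes, 24 of 27 members rose (25 adjusted over the list alone, camera adjusted p = 1.36e-11 preset, 0.237 estimated). The collagen gene Col3a1 was at 1.56 ± 0.29. Of cell cycle genes, 18 of 27 members rose (20 adjusted over the list alone, camera adjusted p = 5.11e-07 preset, 0.286 estimated). The proliferation marker Mki67 was at 1.36 ± 0.36 and Cdk1 at 1.56 ± 0.32. Interferon-induced genes also rose: 22 of 29 members rose (24 adjusted over the list alone, camera adjusted p = 5.83e-11 preset, 0.237 estimated). Oas3 was at 1.70 ± 0.19. Fgf21, a hormone of fasted or stressed liver, rose 3.45-fold (1.79 ± 0.33, adjusted p = 2.07e-05).

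Metabolic lists held genes that fell on the diet. Of cholesterol synthesis genes, 17 of 22 members fell (21 adjusted over the list alone, camera adjusted p = 1.57e-10 preset, 0.237 estimated). The sterol reductase gene Tm7sf2 was at -1.13 ± 0.16. Of xenobiotic metabolism genes, 9 of 17 members fell (11 adjusted over the list alone), led by Cyp3a11 (-1.90 ± 0.17, adjusted p = 3.22e-13, ENSMUSG00000056035.8, chromosome 5, 145854426 to 145879964) and Cyp2b10 (-3.93 ± 0.52), which belong to families of near-identical copies, so their single-gene values are uncertain (list camera adjusted p = 1.24e-06 preset, 0.141 estimated). Of bile acid genes, 0 of 16 members rose and 8 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.000526 preset, 0.237 estimated). Cyp27a1 was at -0.58 ± 0.11 and the bile salt export pump gene Abcb11 at -0.62 ± 0.12. Of fatty acid oxidation genes, 2 of 26 members rose and 14 fell (2 and 14 adjusted over the list alone, camera adjusted p = 0.000338 preset, 0.311 estimated). The peroxisomal oxidase gene Acox1 was at -0.47 ± 0.09. The 4 largest falls were Myh4, Atp2a1 (-8.03 ± 1.88), Acta1 and Ucp1, genes of muscle and brown fat that were high in 1 chow liver each. Without chow animal 8, at 83.6 CPM of Atp2a1, Atp2a1 was at -0.69 (adjusted p = 0.912), and in DESeq2 at -0.82 (adjusted p = 0.637). Chow animal 8 had 39.9 CPM of Myh4, which had 0 CPM in the other chow livers and in HFD controls, and 104 CPM of Acta1, and chow animal 6 had 102 CPM of Ucp1.

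Semaglutide alone was compared with HFD controls in liver to ask what the drug does without exercise (14 animals each), and 2729 genes passed (1291 higher, 1438 lower). Macrophage markers were lower: 18 of 22 members fell (19 adjusted over the list alone, camera adjusted p = 2.33e-12 preset, 0.508 estimated). Mpeg1 was at -0.75 ± 0.14 and Cd68 at -0.63 ± 0.14. Of lipid-associated macrophage genes, 10 of 15 members fell (10 adjusted over the list alone, camera adjusted p = 1.52e-06 preset, 0.508 estimated). Trem2 was at -1.26 ± 0.28, adjusted p = 0.00103 and the elastase gene Mmp12 at -2.05 ± 0.43. Of cell cycle genes, 19 of 27 members fell (20 adjusted over the list alone, camera adjusted p = 6.09e-12 preset, 0.508 estimated). Ccnb1 was at -1.73 ± 0.38. Of matrix genes, 7 of 27 members fell (9 adjusted over the list alone, camera adjusted p = 1.52e-06 preset, 0.589 estimated). Postn was at -0.87 ± 0.17 and Tnc at -1.18 ± 0.24. Pparg and its lipid droplet target Cidec, which fatty hepatocytes express, fell (-0.74 ± 0.13 and -2.05 ± 0.41, adjusted p = 0.000279, ENSMUSG00000030278.11, chromosome 6, 113424634 to 113435760).

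Genes with sex-biased expression in mouse liver moved in these male animals. Of female-biased genes, 8 of 12 members rose (8 adjusted over the list alone, camera adjusted p = 0.000374 preset, 0.508 estimated). The transcription factor Cux2 was at 1.57 ± 0.36 and the monooxygenase gene Fmo3 at 3.73 ± 0.86, adjusted p = 0.00155, ENSMUSG00000026691.10, chromosome 1, 162953800 to 162984528. Of male-biased genes, 4 of 14 members fell (5 adjusted over the list alone, camera adjusted p = 0.0306 preset, 0.766 estimated). Selenbp2 was at -2.43 ± 0.59. Sprr1a (-4.06 ± 0.70, adjusted p = 3.1e-05, ENSMUSG00000050359.7, chromosome 3, 92483952 to 92485895) and Ephb2 (-2.43 ± 0.49) were among the largest falls, and the glutathione transferase gene Gsta1, of a family of close copies, was at -2.32 ± 0.38. The 4 largest rises were Ucp1 (5.86 ± 1.30), Star (5.42 ± 1.02), Cyp21a1 (4.32 ± 1.06) and Plin1 (4.10 ± 1.08), genes of brown fat, adrenal and adipose tissue. They followed 1 library, semaglutide animal 43, with 690 CPM of Star and 512 of Cyp21a1. Without it and chow animal 6, Star was at 0.37 (adjusted p = 0.303), Ucp1 at 1.84 (adjusted p = 0.15) and Cyp21a1 at -2.85 (adjusted p = 0.000488).

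Running alone (15 animals) was compared with HFD controls (14) to ask what exercise does without the drug. edgeR called 0 liver genes, with 887 at an unadjusted p under 0.05, and DESeq2 called 0. Trem2, for which both semaglutide groups passed, was at -0.67 ± 0.27, adjusted p = 0.82, Cd68 at -0.33 ± 0.14, adjusted p = 0.82 and Cidec at -0.70 ± 0.38, adjusted p = 0.82.

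The combined treatment was compared with HFD controls to ask for the joint effect (14 animals each), and 4763 liver genes passed (2449 higher, 2314 lower). Matrix genes were lower: 22 of 27 members fell (23 adjusted over the list alone, camera adjusted p = 6.2e-10 preset, 0.66 estimated). Col1a1 was at -1.90 ± 0.34, adjusted p = 2.71e-05, ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042 and Postn at -1.09 ± 0.17. Of cell cycle genes, 22 of 27 members fell (22 adjusted over the list alone, camera adjusted p = 1.06e-11 preset, 0.66 estimated). Mcm2 was at -0.86 ± 0.13. Of macrophage markers, 19 of 22 members fell (20 adjusted over the list alone, camera adjusted p = 1.02e-08 preset, 0.66 estimated). Of lipid-associated macrophage genes, 13 of 15 members fell (13 adjusted over the list alone, camera adjusted p = 1.33e-06 preset, 0.66 estimated). Mmp12 was at -2.47 ± 0.44 and Trem2 at -1.42 ± 0.28. Of fatty acid synthesis genes, 1 of 21 members rose and 8 fell (1 and 10 adjusted over the list alone, camera adjusted p = 0.0103 preset, 0.745 estimated). The desaturase gene Scd1 was at -1.05 ± 0.25 and Acacb at -0.94 ± 0.27. Genes of protein folding in the endoplasmic reticulum were higher: 12 of 20 members rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.0254 preset, 0.745 estimated). Creld2 was at 1.34 ± 0.35 and Hsp90b1 at 0.59 ± 0.15. Of clock genes, 5 of 17 members rose (5 adjusted over the list alone, camera adjusted p = 0.953 preset, 0.983 estimated, with a median of -0.02, a mean of 0.10 and a test direction up). Nfil3 was at 1.16 ± 0.22 and Cry1, a repressor of the clock, at 1.16 ± 0.28.

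Female-biased liver genes were again higher under the combined treatment: 8 of 12 members rose (8 adjusted over the list alone, camera adjusted p = 0.0438 preset, 0.745 estimated). Fmo3 was at 5.50 ± 0.87, adjusted p = 2.2e-06 and Cyp2c69 at 3.73 ± 0.77. The largest falls were Sprr1a (-5.76 ± 0.83, adjusted p = 3.62e-07), Ly6d (-3.89 ± 0.60), Ephb2 (-3.52 ± 0.53, adjusted p = 1.05e-06, ENSMUSG00000028664.14, chromosome 4, 136647539 to 136835988) and Gsta1 (-3.40 ± 0.41). Cd36, a fatty acid transporter, fell (-0.85 ± 0.18, adjusted p = 0.000278), and so did the lipid droplet gene Cidec (-2.76 ± 0.43). Ndufa12, 1 of the mitochondrial complex genes, was at -0.66 ± 0.13, while of the oxidative phosphorylation list 18 of 58 members rose and 4 fell (20 and 4 adjusted over the list alone, camera adjusted p = 0.00153 preset, 0.745 estimated). Ndufa12 varied within groups together with Gpx1, and averaged 23 CPM (SD 10.5, n = 14) under the combined treatment against 36.4 (SD 4.37, n = 14) in HFD controls. The muscle genes Myh4 (adjusted p = 0.00377) and Atp2a1 (6.95 ± 1.86) had the largest rises, and combined-treatment animals 80 and 75 had 70.6 and 44.3 CPM of Myh4 against 0 in HFD controls.

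**Figure D2:**
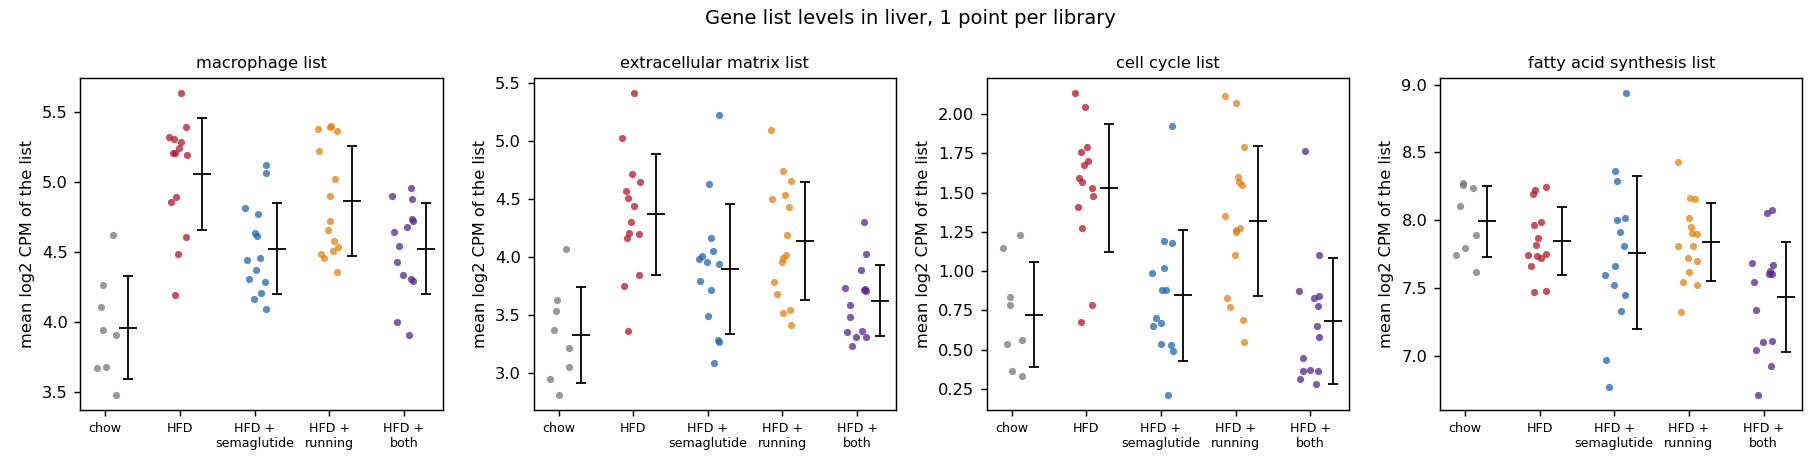
Mean log2 CPM of 4 gene lists in each liver library, by group, with the group mean and SD beside the points (vertical axis in log2 CPM). The macrophage, matrix and cell cycle lists are higher in HFD controls than in chow and lower again in the semaglutide and combined-treatment groups.

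Adding a wheel to semaglutide changed 201 liver genes (109 higher, 92 lower, 14 animals each). Of endothelial markers, 1 of 17 members fell (9 adjusted over the list alone, camera adjusted p = 2.11e-08 preset, 0.227 estimated). Of fatty acid synthesis genes, 1 of 21 members fell (9 adjusted over the list alone, camera adjusted p = 2.24e-05 preset, 0.768 estimated), and of the unfolded protein response list, 0 of 20 members rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.000431 preset, 0.768 estimated). Dnajb11, a chaperone gene, rose (0.52 ± 0.14, adjusted p = 0.0325, ENSMUSG00000004460.17, chromosome 16, 22857845 to 22879634), and Ldlr fell (-0.27 ± 0.07, adjusted p = 0.0315). Star (-4.62 ± 0.96) and Cyp21a1 (-5.99 ± 1.22) led the falls, and were at 0.43 and 1.15 without semaglutide animal 43 alone, when 102 genes passed. Dnajb11 and Ldlr kept about their size without it (0.49 and -0.26) and missed the threshold (adjusted p = 0.072 and 0.0578). Without combined-treatment animal 79, 160 genes passed, and Ldlr was at -0.24 (adjusted p = 0.0674). Without liver animals 6 and 43, 93 genes passed, 91 of them shared. A fit of these groups alone called 59 genes, and a fit with the level of Ndufa12 and Gpx1 as a covariate called 413.

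Adding semaglutide to a wheel changed 2222 liver genes (1087 higher, 1135 lower, 14 against 15 animals). Of cell cycle genes, 14 of 27 members fell (23 adjusted over the list alone, camera adjusted p = 3.26e-11 preset, 0.679 estimated), and of matrix genes, 12 of 27 members fell (17 adjusted over the list alone, camera adjusted p = 1.07e-07 preset, 0.679 estimated). Fmo3 rose (5.46 ± 0.84, adjusted p = 9.42e-06) and Ephb2 fell (-3.03 ± 0.52, adjusted p = 5.29e-05). Of the female-biased list, 6 of 12 members rose (10 adjusted over the list alone, camera adjusted p = 0.00538 preset, 0.679 estimated). The interaction, which asks whether the joint effect differs from the sum of both single effects, called 0 liver genes in edgeR, with 831 at an unadjusted p under 0.05, and 0 in DESeq2.

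The share of diet-changed liver genes that a treatment moved the opposite way was taken with the HFD controls divided at random in 2 equal parts, 1 for the diet and 1 for the treatment. Over 10 such splits, with 2823 to 4488 genes called for the diet, the median share was 75.15% for semaglutide (68.5 to 84.1%), 70.1% for running (53.9 to 79.8%) and 78.3% for both (74.8 to 83.9%). The median ratio of the treatment's change to the diet's was 0.257, 0.103 and 0.334. With the controls shared, the shares were 81.1%, 82.5% and 82.1%, against 57.6 to 60.3% for simulated groups with no treatment effect (5072 to 5113 genes called for the diet). With divided controls, simulated liver groups with no effect gave 48.9 to 51.1%. This range comes from 3 splits of 1 simulated set. Simulated genes were drawn independently, so it does not show how far correlated genes can move a share by chance. In pgWAT, divided controls gave 48.2%, 38.5% and 46.75% over 4 splits, where shared controls gave 75.3%, 78.6% and 85.7% (simulated with no effect 66 to 70.4%, over 2354 to 2487 genes against 817). In muscle, with a median of 37 genes called for the diet over 5 splits, divided controls gave 42.4%, 21.2% and 24.2% (shared 53.1%, 30.6% and 34.7%, simulated 71.4 to 75% over 541 to 656 genes against 49). In aorta, with a median of 55.5 genes over 2 splits, they gave 38%, 63.2% and 40.25% (shared 88.7%, 96.2% and 92.5%, simulated 69.4 to 74.3% over 1282 to 1410 genes against 53).

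In muscle, transcripts made by the liver differed between groups. Of 11 hepatocyte secretory genes such as Alb (albumin), 11 fell with semaglutide, 11 with running and 11 with both against HFD controls (11, 11 and 11 adjusted over the list alone). Alb was at -3.48 ± 0.49, adjusted p = 4.76e-07, ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602 with semaglutide and -3.76 ± 0.51, adjusted p = 2.78e-07 with both, and Fgb, for fibrinogen, at -4.30 ± 0.53, adjusted p = 1.59e-08 with running. With the liver RNA share as a covariate, Alb was at 0.17 (adjusted p = 0.893) with semaglutide. Alb is itself the most abundant gene of that share (69000 CPM in liver), so a value near 0 follows from the covariate and adds no evidence. The list had camera adjusted p = 2.8e-17, 1.22e-16 and 3.8e-11, and adjusted p = 0.0997, 0.0905 and 0.406 with an estimated correlation. Measured against liver levels of these genes, the liver RNA share of muscle libraries had medians of 0.301% in chow (n = 8), 0.0892% in HFD controls (n = 15), 0.0103% with semaglutide (n = 15), 0.00598% with running (n = 15) and 0.00501% with both (n = 14). Liver RNA at the highest group's share could supply 5% or more of the lowest group's level for 760 of 14510 muscle genes, and counts without these genes are given beside each comparison.

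**Figure D3:**
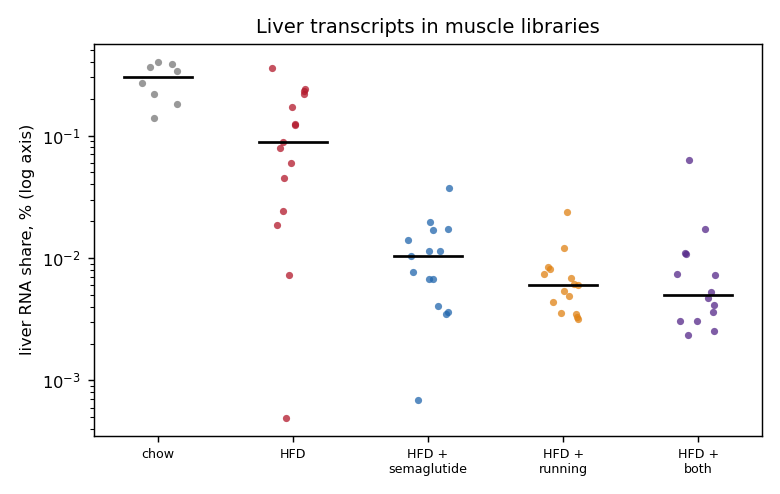
Liver RNA share of each muscle library in percent (log axis), by group, with group medians as lines. Chow libraries range from 0.138 to 0.4%, and the 3 treated groups have medians of 0.0103% or less.

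In muscle, 49 genes were called between 15 HFD controls and 8 chow animals (23 higher, 26 lower), a count for which chance cannot be excluded, or 18 without the genes that liver RNA could set. Of fatty acid oxidation genes, 6 of 25 members rose and 1 fell (18 and 4 adjusted over the list alone, camera adjusted p = 1.92e-08 preset, 0.314 estimated). The mitochondrial isomerase genes Eci2 (0.41 ± 0.07, adjusted p = 0.000949, ENSMUSG00000021417.15, chromosome 13, 34977748 to 35027096) and Ech1 (0.65 ± 0.14) rose, as did Pdk4 (1.04 ± 0.26), which restrains glucose oxidation. Fabp3 (0.86 ± 0.20) and Cd36 (0.59 ± 0.14), which carry fatty acids, rose as well. Without HFD animal 24, 29 genes passed, and Pdk4, Fabp3 and Cd36 kept about their size (0.99, 0.82 and 0.57) but missed the threshold (adjusted p = 0.0707, 0.0565 and 0.0505). Cyp3a11 fell (-2.01 ± 0.38), as did the cholesterol synthesis gene Dhcr24 (-0.96 ± 0.17, adjusted p = 0.000949), both genes that liver RNA could set. Of the cholesterol synthesis list, 1 of 20 members fell (3 adjusted over the list alone), with 11 that liver RNA could set (camera adjusted p = 5.14e-05 preset, 0.0046 estimated). The chow group has the highest liver RNA share, and 5 genes passed with that share as a covariate. Eci2, Ech1, Pdk4, Fabp3 and Cd36 then kept about their size (0.36, 0.62, 1.02, 0.80 and 0.55) but missed the threshold (adjusted p = 0.0708 to 0.247), as did Pdk4 and Fabp3 without the genes that liver RNA could set (adjusted p = 0.0804 and 0.0586). Cyp3a11 was at -0.81 (adjusted p = 0.6) and Dhcr24 at -0.74 (adjusted p = 0.152) with the covariate.

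Semaglutide changed 260 muscle genes (33 higher, 227 lower, 15 animals each), and 6 without the genes that liver RNA could set. Myh3 (-2.37 ± 0.52, adjusted p = 0.00217, ENSMUSG00000020908.14, chromosome 11, 67078300 to 67102291) and Myh8 (-1.50 ± 0.40, adjusted p = 0.0236), myosins of embryonic and newborn muscle, passed because of 1 library, HFD control animal 24, with 174 CPM of Myh3 where the other HFD controls had at most 6.1. Without it Myh3 was at -0.23 (adjusted p = 0.935) and Myh8 at 0.07 (adjusted p = 0.983), and DESeq2 gave -0.22 and 0.06. Both lie in the denervation list, where 2 of 14 members fell (2 adjusted over the list alone, camera adjusted p = 0.695 preset, 0.9 estimated). Lgals3, a macrophage galectin, fell (-1.05 ± 0.24, adjusted p = 0.00424), and kept its size but missed the threshold without the genes that liver RNA could set (-1.05, adjusted p = 0.0697), with the liver RNA share as a covariate (-1.17, adjusted p = 0.106) and in a fit of both groups alone (-1.05, adjusted p = 0.115). Of the lipid-associated macrophage list, 5 of 15 members fell (7 adjusted over the list alone), among them Trem2 (-1.50 ± 0.31) and Mmp12 (-2.54 ± 0.52), which liver RNA could set (camera adjusted p = 2.07e-06 preset, 0.124 estimated). A fit of both groups alone called 64 genes.

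Running changed 234 muscle genes (40 higher, 194 lower, 15 animals each). Without the genes that liver RNA could set edgeR called 0, with 1246 at an unadjusted p under 0.05. Genes of oxidative phosphorylation were higher as a list: 1 of 58 members rose (26 adjusted over the list alone, camera adjusted p = 2.36e-24 preset, 0.263 estimated). Ndufa9 was at 0.22 ± 0.06, adjusted p = 0.0488. The citrate synthase gene Cs, a marker of mitochondrial content, rose (0.19 ± 0.05, adjusted p = 0.0111, ENSMUSG00000005683.8, chromosome 10, 128337734 to 128362479). Of immediate early genes, 1 of 14 members fell (12 adjusted over the list alone, camera adjusted p = 1.44e-10 preset, 0.0905 estimated). Fosb was at -1.33 ± 0.33, adjusted p = 0.0132. Myh3 (-2.19 ± 0.52, adjusted p = 0.00702) and Myh8 (-1.49 ± 0.40, adjusted p = 0.0279) passed through HFD animal 24, without which they were at -0.04 and 0.07 (adjusted p = 0.979 and 0.932) and Ndufa9 was at 0.22 (adjusted p = 0.0511). A fit of both groups alone called 28 genes.

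The combined treatment changed 553 muscle genes (196 higher, 357 lower, 14 against 15 animals), and 211 (101 higher, 110 lower) without the genes that liver RNA could set. Of oxidative phosphorylation genes, 9 of 58 members rose (31 adjusted over the list alone, camera adjusted p = 8.16e-18 preset, 0.513 estimated). Uqcrb was at 0.27 ± 0.07 and Sdhc at 0.20 ± 0.06. The exercise-responsive receptor gene Nr4a3 rose 4.19-fold (2.07 ± 0.47, adjusted p = 0.00261, ENSMUSG00000028341.9, chromosome 4, 48045153 to 48086447), Ppargc1a, a regulator of mitochondrial biogenesis, was at 0.32 ± 0.10, adjusted p = 0.0361, and the cardiac actin gene Actc1 at 1.05 ± 0.27, adjusted p = 0.0106. The lysyl oxidase gene Lox fell (-0.74 ± 0.20, adjusted p = 0.0141). Without HFD animal 24, Myh3 (-2.41 ± 0.54, adjusted p = 0.00244) and Myh8 (-1.51 ± 0.41, adjusted p = 0.0187) were at -0.27 and 0.05 (adjusted p = 0.664 and 0.912), while Ppargc1a kept its size (0.32, adjusted p = 0.0517). Leptin (Lep, -1.98 ± 0.47, adjusted p = 0.00527, ENSMUSG00000059201.12, chromosome 6, 29060220 to 29073877) and the lipid droplet gene Plin4 (-0.29 ± 0.08) fell, and of the adipocyte list 2 of 17 members fell (3 adjusted over the list alone, camera adjusted p = 0.0475 preset, 0.775 estimated). Of clock genes, 1 of 17 members rose and 2 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.0475 preset, 0.513 estimated). Per1 was at -0.93 ± 0.23 and Cry1 at 0.24 ± 0.07. Without the genes that liver RNA could set, Sdhc, Ppargc1a and Cry1 kept about their size (0.19, 0.32 and 0.24) but missed the threshold (adjusted p = 0.0567, 0.0736 and 0.076). With the liver RNA share as a covariate 35 genes passed, 25 of them shared, and Uqcrb, Sdhc, Nr4a3, Ppargc1a, Actc1, Lox, Lep, Plin4, Per1 and Cry1 did not (adjusted p = 0.0833 to 0.436). A fit of both groups alone called 112 genes, where Lep and Per1 passed and the other 8 of these did not (adjusted p = 0.0511 to 0.169). With the adipocyte score as a covariate Plin4, Lox, Sdhc, Ppargc1a and Cry1 were at -0.23, -0.54, 0.18, 0.30 and 0.24 and missed it (adjusted p = 0.0513 to 0.0781).

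Against semaglutide alone, the combined treatment called 9 muscle genes (6 higher, 3 lower), a count for which chance cannot be excluded, or 198 in DESeq2 and 3 without the genes that liver RNA could set, when Rgs2 was at 0.815 (adjusted p = 0.0534). Oxidative phosphorylation genes were higher as a list: 0 of 58 members rose (47 adjusted over the list alone, camera adjusted p = 1.1e-25 preset, 0.194 estimated). Ndufaf4, an assembly factor of respiratory complex I, rose (0.25 ± 0.05, adjusted p = 0.0329, ENSMUSG00000028261.13, chromosome 4, 24898083 to 24905001), as did Rgs2 (0.82 ± 0.18, adjusted p = 0.0425), and the splicing factor gene Prpf8 fell (-0.22 ± 0.05, adjusted p = 0.0425). A fit of both groups alone called 0, with 1780 at an unadjusted p under 0.05. Against running alone, edgeR called 0 genes, with 1032 at an unadjusted p under 0.05, and DESeq2 10, and 0 without the genes that liver RNA could set (edgeR, 970 at an unadjusted p under 0.05). The interaction called 61 genes (60 higher, 1 lower), with all 11 of 11 hepatocyte genes higher (11 adjusted over the list alone; camera adjusted p = 7.41e-10 preset, 0.29 estimated). Without the genes that liver RNA could set, the interaction called 0 in edgeR, with 350 at an unadjusted p under 0.05.

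In pgWAT, 3 features of the libraries differed between groups. Markers of ciliated and ductal epithelium, a list written after the values were seen, exceeded a mean log2 CPM of 3 in semaglutide animals 40 and 43 and combined-treatment animals 70, 71, 74 and 80, and in 0 of the 7 chow, 10 HFD control and 10 running libraries. The liver RNA share had medians of 2.44% in chow (0.598 to 10.3%, n = 7), 0.444% in HFD controls (0.0869 to 1.39%, n = 10), 0.601% with semaglutide (0.083 to 1.46%, n = 7), 0.921% with running (0.224 to 10.9%, n = 10) and 0.289% with both (0.011 to 7.65%, n = 8). With both, animal 82 had 7.65% and the others at most 0.593%. The libraries of combined-treatment animals 70 and 71 differed by a mean chi-square of 2.62 per gene, against 11.83 for the next closest pair and a median of 67.43 over all 861 pairs.

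The diet changed 817 pgWAT genes (426 higher, 391 lower, 10 HFD controls against 7 chow), or 690 (275 higher, 415 lower) with DESeq2 size factors. Lymphocyte genes were higher on the diet: 9 of 18 members rose (17 adjusted over the list alone, camera adjusted p = 1.2e-07 preset, 0.388 estimated). The T-cell gene Cd3g was at 1.56 ± 0.34, adjusted p = 0.0214, ENSMUSG00000002033.14, chromosome 9, 44969572 to 44980431. Of interferon genes, 7 of 29 members rose (16 adjusted over the list alone, camera adjusted p = 2.45e-08 preset, 0.388 estimated). Oas1a was at 0.87 ± 0.20. Of lipid-associated macrophage genes, 1 of 16 members rose and 0 fell (8 and 1 adjusted over the list alone, camera adjusted p = 1.94e-07 preset, 0.388 estimated). The fatty acid binding protein gene Fabp5 was at 0.63 ± 0.18. The adipokine gene Cfd fell (-2.13 ± 0.39, adjusted p = 0.0129, ENSMUSG00000061780.6, chromosome 10, 79890853 to 79892655), and of the adipocyte list 1 of 17 members fell (3 adjusted over the list alone, camera adjusted p = 4.51e-06 preset, 0.4 estimated). Thrsp, an activator of fat synthesis, was at -1.14 ± 0.31. Of hepatocyte genes, 5 of 11 members fell (11 adjusted over the list alone, camera adjusted p = 2.45e-08 preset, 0.388 estimated). Serpina1c, of a family of near-identical copies, was at -3.37 ± 0.87. Without the 3379 genes that liver RNA could set 27 genes passed, and Oas1a, Fabp5 and Thrsp kept about their size (0.83, 0.59 and -1.19) but missed the threshold (adjusted p = 0.0598, 0.083 and 0.0626). With the liver RNA share as a covariate 2 genes passed. Cd3g, Oas1a, Cfd, Fabp5 and Thrsp were then at 1.53, 0.89, -1.86, 0.49 and -1.05 (adjusted p = 0.137 to 0.239), and Serpina1c, itself 1 of the genes of that share, at -0.65 (adjusted p = 0.225).

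Semaglutide alone (7 animals) called 0 pgWAT genes in edgeR against HFD controls (10), with 2202 at an unadjusted p under 0.05, and 108 in DESeq2. Of epididymal duct genes, 0 of 11 members rose (3 adjusted over the list alone, camera adjusted p = 0.043 preset, 0.73 estimated, with a median of -0.42, a mean of 0.36 and a test direction up). Gpx5 was at 4.08 ± 1.20, adjusted p = 0.178, or 1.88 without animal 40. Running alone (10 animals) called 0 in edgeR, with 1364 at an unadjusted p under 0.05, and 5 in DESeq2. Of hepatocyte genes, 0 of 11 members rose (11 adjusted over the list alone, camera adjusted p = 1.45e-07 preset, 0.706 estimated). Apoa1 was at 2.49 ± 0.84, adjusted p = 0.553.

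The combined treatment changed 1924 pgWAT genes (1137 higher, 787 lower, 8 against 10 animals). Matrix genes were lower: 17 of 27 members fell (21 adjusted over the list alone, camera adjusted p = 2.88e-16 preset, 0.131 estimated). Col6a3, a collagen chain of fat, was at -0.98 ± 0.19, adjusted p = 0.00184, ENSMUSG00000048126.16, chromosome 1, 90765923 to 90843971 and Col5a2 at -0.84 ± 0.19. Of inflammatory mediators, 3 of 20 members fell (3 adjusted over the list alone, camera adjusted p = 0.000366 preset, 0.736 estimated). The monocyte chemokine gene Ccl2 was at -1.69 ± 0.29, adjusted p = 0.000829, ENSMUSG00000035385.5, chromosome 11, 82035571 to 82037453 and Il1rn at -1.47 ± 0.38. Of cell cycle genes, 6 of 27 members fell (24 adjusted over the list alone, camera adjusted p = 8.23e-12 preset, 0.718 estimated). Cdk1 was at -0.95 ± 0.29. Cfd (1.49 ± 0.38, adjusted p = 0.00991) and Retn (1.06 ± 0.34) rose, and of the adipocyte list 2 of 17 members rose (3 adjusted over the list alone, camera adjusted p = 0.0288 preset, 0.815 estimated). The lipid droplet coat gene Plin2 fell (-0.82 ± 0.18, adjusted p = 0.00346). The largest rises included the ciliary genes Ccdc153 (adjusted p = 0.00371), at a mean of 30.7 CPM against 0 in HFD controls, and Sntn (adjusted p = 0.0044), at 7.41 against 0.013, and epididymal Gpx5 was at 3.89 ± 1.17, adjusted p = 0.0278. Gpx5 was at 1.82 (adjusted p = 0.158) with the epididymis score as a covariate, and Ccdc153 and Sntn at 3.94 and 0.52 (adjusted p = 0.0949 and 0.89) with the duct score. Without the 6 libraries highest in duct markers, which leaves 4 combined-treatment animals, 54 genes passed (30 higher, 24 lower). Col5a2, Ccl2, Il1rn, Cdk1, Cfd, Retn, Plin2 and Gpx5 kept about their size (-0.81, -1.43, -1.34, -1.09, 1.57, 1.26, -0.76 and 4.03) but missed the threshold (adjusted p = 0.09 to 0.196). Calls numbered 1345 with animals 70 and 71 counted as 1.

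**Figure D4:**
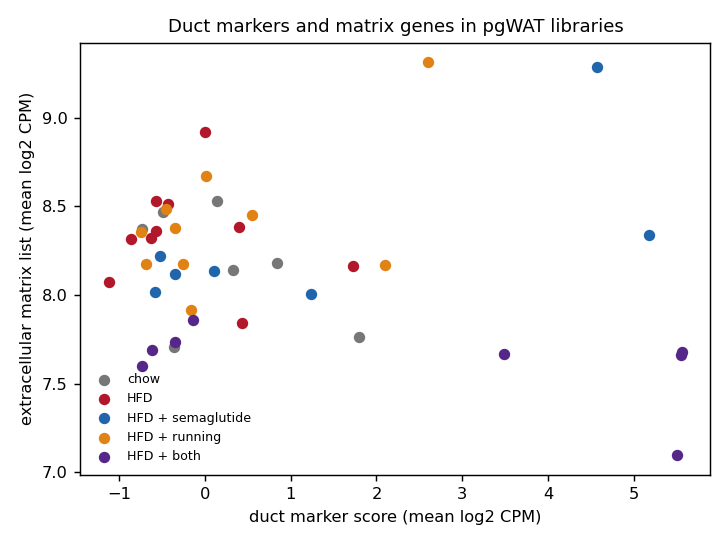
Mean log2 CPM of the extracellular matrix list (vertical axis) against that of the duct marker list (horizontal axis) in each pgWAT library, coloured by group. Matrix values of the combined-treatment animals lie at 7.86 or below.

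Against semaglutide alone, the combined treatment called 0 pgWAT genes in edgeR, with 1057 at an unadjusted p under 0.05, and 10 in DESeq2 (8 against 7 animals). Matrix genes were lower as a list: 0 of 27 members fell (22 adjusted over the list alone, camera adjusted p = 7e-29 preset, 0.00755 estimated). Semaglutide animal 40 has a matrix score above and combined-treatment animal 80 one below the others of its group. Over the list alone 7 fell without animal 40, and 0 without the libraries highest in duct markers, which include both. Against running alone 1618 genes passed (903 higher, 715 lower), or 20 without the libraries highest in duct markers and 916 with animals 70 and 71 counted as 1. Of matrix genes, 18 of 27 members fell (24 adjusted over the list alone, camera adjusted p = 2.01e-18 preset, 0.0778 estimated), and of macrophage markers, 3 of 22 members fell (8 adjusted over the list alone, camera adjusted p = 3.62e-07 preset, 0.541 estimated). Cnn1, a smooth muscle calponin, passed (-5.96 ± 1.52, adjusted p = 0.0139) because of running animal 62, at 1060 CPM, and was at -0.66 (adjusted p = 0.676) without it. The interaction called 1 gene, a count for which chance cannot be excluded: Ptgs2, the inducible cyclooxygenase (-12.39 ± 2.26, adjusted p = 0.0493, ENSMUSG00000032487.8, chromosome 1, 150100031 to 150108227), and 0 genes without the libraries highest in duct markers (edgeR, 715 at an unadjusted p under 0.05). Ptgs2 was high in running animal 62 and semaglutide animal 40 (1580 and 564 CPM), and 0 genes passed without either (edgeR, 1002 and 793 at an unadjusted p under 0.05). Ptgs2 was at -6.47 without 1 or the other, and at -0.53 in DESeq2 (adjusted p = 0.941). Of the matrix list, 0 of 27 members fell (15 adjusted over the list alone) for the interaction (camera adjusted p = 6.78e-23 preset, 0.0205 estimated), 10 over the list alone without animal 40 and 0 without the libraries highest in duct markers.

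In aorta, the diet changed 53 genes (4 higher, 49 lower, 7 HFD controls against 4 chow). The aorta libraries also held transcripts of fat and skeletal muscle. In chow and HFD controls, the mean log2 CPM was 7.86 and 7.61 for adipocyte markers and 6.44 and 6.13 for thermogenic genes. It was 7.58 and 7.44 for skeletal muscle genes. Which cells the changes in aorta come from was not tested. Of fatty acid synthesis genes, 9 of 21 members fell (16 adjusted over the list alone, camera adjusted p = 3.73e-14 preset, 0.193 estimated). Acss2, which makes acetyl-CoA, was at -1.46 ± 0.24, adjusted p = 0.00882, ENSMUSG00000027605.18, chromosome 2, 155517948 to 155585724 and Scd1 at -1.66 ± 0.32. Of cholesterol synthesis genes, 5 of 22 members fell (14 adjusted over the list alone, camera adjusted p = 9.21e-10 preset, 0.193 estimated). The squalene synthase gene Fdft1 was at -0.95 ± 0.17, adjusted p = 0.0118, ENSMUSG00000021273.10, chromosome 14, 63145150 to 63179578. The chemokine gene Ccl7 rose (1.46 ± 0.32, adjusted p = 0.0381) and Fabp5 fell (-0.43 ± 0.10, adjusted p = 0.0389). Of interferon genes, 0 of 29 members rose (5 adjusted over the list alone, camera adjusted p = 6.42e-10 preset, 0.463 estimated). Leaving out chow animal 1, 3, 6 or 7 gave 28, 4, 40 or 96 genes, and without animal 3 the 5 genes named here did not pass, with Scd1 at -1.05 (adjusted p = 0.136). Separately, a fit of both groups alone gave 0 (edgeR, 2193 at an unadjusted p under 0.05), and DESeq2 called 208. Excess fat was removed from 2 aorta samples, chow animal 1 and HFD animal 27, and 88 genes passed without them.

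Semaglutide (8 animals) and running (9) each called 0 aorta genes in edgeR against HFD controls (7), with 1050 and 636 at an unadjusted p under 0.05, and 0 in DESeq2. Of hepatocyte genes, 0 of 11 members fell (10 adjusted over the list alone) with semaglutide (camera adjusted p = 1.92e-09 preset, 0.357 estimated) and 0 of 11 members fell (11 adjusted over the list alone) with running (camera adjusted p = 1.62e-10 preset, 0.417 estimated). Red blood cell genes were lower with running over the list alone: 0 of 6 members fell (5 adjusted over the list alone, camera adjusted p = 1.61e-09 preset, 0.143 estimated). The combined treatment (7 animals) called 5 genes, a count for which chance cannot be excluded, all lower: Sncg, a synuclein of nerve and fat (-1.24 ± 0.24, adjusted p = 0.0405, ENSMUSG00000023064.4, chromosome 14, 34370274 to 34374789), and 4 chosen after their values were seen. These were the serotonin synthesis gene Tph2 (-2.95 ± 0.53, adjusted p = 0.0233), the cartilage protein gene Crtac1 (-1.62 ± 0.27, adjusted p = 0.0154), Srpx2 (-1.28 ± 0.23, adjusted p = 0.0224) and the unnamed 1700047G03Rik (-2.15 ± 0.42, adjusted p = 0.0423). Of matrix genes, 0 of 27 members rose and 0 fell (1 and 21 adjusted over the list alone, camera adjusted p = 8.36e-15 preset, 0.472 estimated). Thbs2 was at -0.77 ± 0.20, adjusted p = 0.197. Of cholesterol synthesis genes, 0 of 22 members rose (3 adjusted over the list alone, camera adjusted p = 2.39e-08 preset, 0.337 estimated). Cyp51 was at 0.60 ± 0.13, adjusted p = 0.0911. DESeq2 called 47 genes, and 90 passed in a fit of both groups alone. With the liver RNA share as a covariate edgeR called 0, with 1265 at an unadjusted p under 0.05. The 5 genes kept about their size: Sncg was at -1.20 (adjusted p = 0.141), Tph2, Crtac1 and Srpx2 at -2.90, -1.64 and -1.28 (adjusted p = 0.0815 each) and 1700047G03Rik at -2.04 (adjusted p = 0.165).

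Against semaglutide alone, the combined treatment called 0 aorta genes in edgeR, with 939 at an unadjusted p under 0.05, and 0 in DESeq2. Against running alone 16 genes passed (1 higher, 15 lower), or 68 in DESeq2. Lep fell (-1.58 ± 0.33, adjusted p = 0.0392), as did the natriuretic peptide clearance receptor gene Npr3 (-1.47 ± 0.29, adjusted p = 0.0256, ENSMUSG00000022206.7, chromosome 15, 11839896 to 11907287) and the chemokine gene Cxcl14 (-1.17 ± 0.22, adjusted p = 0.0251). Lep and Npr3 kept about their size with the adipocyte score as a covariate (-1.43 and -1.32, adjusted p = 0.117 and 0.0609), and missed the threshold there and without a low-count filter (adjusted p = 0.113 and 0.0837). Of endothelial markers, 0 of 17 members fell (9 adjusted over the list alone, camera adjusted p = 3.37e-07 preset, 0.427 estimated). The interaction called 0 genes in edgeR, with 864 at an unadjusted p under 0.05, and 0 in DESeq2.

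Whether animals with higher levels in 1 tissue had higher levels in another was asked for 6 gene lists in 6 tissue pairs (36 relations), after group means were removed. The clock gene list was correlated between liver and muscle of 65 animals (r = 0.507, permutation p = 7e-05, adjusted p = 0.00252, rho = 0.486, permutation p = 1e-04), with r = 0.422 (permutation p = 0.00086) without the 2 animals farthest from the median. Interferon genes were correlated between muscle and pgWAT of 42 animals (r = 0.485, permutation p = 0.00249, adjusted p = 0.0448, rho = 0.544, permutation p = 0.00052), with r = 0.491 (permutation p = 0.00277) without the 2 animals farthest from the median. The other 34 relations did not pass after adjustment, including interferon genes between pgWAT and aorta (21 animals, r = 0.64, permutation p = 0.00873, adjusted p = 0.0756).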

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

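Tests chosen after the result was seen are the calls left in muscle without genes that liver RNA could set, the change of these calls with the liver RNA share as a covariate, every test on pgWAT, the covariate of Ndufa12 and Gpx1, the fits without liver animals 6 and 43, and the correlation of within-group variation with transcript length.

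Liver transcripts were lower in muscle of every treated group than in HFD controls. Of 87 genes abundant in liver and nearly absent from muscle of running animals, 98.9% had a ratio of HFD control muscle to liver within 2-fold of their median ratio, 0.117%. A proportional copy of liver RNA needs this, and it argues against expression by muscle cells that the treatments lowered, which would not keep the proportions of liver. Liver RNA cannot be the whole of the combined treatment's effect on muscle, since 211 of its 553 calls passed without the genes it could set. With the liver RNA share as a covariate 17 of the 211 passed. Over the 211, the log2 fold change with this covariate was a median of 0.99 of that without it (10th to 90th percentile 0.73 to 1.23), in the same direction for 211 of 211. Their standard errors were a median of 1.35 times as large, since share and group go together, so the lost calls go with larger errors rather than smaller changes. Library numbers run group by group, with muscle (68 to 134) after liver (1 to 67), so the order of the libraries coincides with the groups. Whether the RNA came with dissection, with plasma or during library preparation was not tested, so a candidate source is liver RNA by an unknown route.

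The combined treatment called 1924 genes in pgWAT, and 4 of its 8 libraries were high in duct markers. Without those libraries the lower calls kept a median of 0.87 of their log2 fold change (10th to 90th percentile 0.64 to 1.19, 787 genes), which argues against duct tissue as the cause of the falls, while the higher calls kept 0.61 (-0.14 to 1.14, 1050 of 1137 genes, the others not being tested without those libraries), so duct tissue may lie behind part of the rises and cannot be told apart with 4 animals left. Counting the near-identical libraries of animals 70 and 71 as 1 kept 68.3% of the calls, and leaving out genes that liver RNA could set kept 74.3%, so neither was the whole cause. A biological effect of the treatment on fat stays open for the calls that remained. Why libraries 70 and 71 are alike was not tested.

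Adding a wheel to semaglutide called 201 liver genes, and 45.3% of them were called without liver animals 6 and 43, which carry transcripts of other tissues. The fit without them has fewer animals, so RNA of other tissues and lost depth cannot be told apart as the reason. With the level of Ndufa12 and Gpx1 as a covariate 69.2% of the calls were kept, and over called genes the log2 fold change was not related to transcript length (rank correlation across genes 0.02), which argues against either as the whole cause. Within groups, genes that varied with Ndufa12 and Gpx1 tended to be shorter (rank correlation -0.41 in liver, -0.25 in muscle, -0.11 in pgWAT, -0.27 in aorta), as a length effect between libraries may give. The order of library numbers was related to this level by a rank correlation of 0.13 within liver groups (permutation p = 0.314), -0.2 in muscle (p = 0.135), 0.23 in pgWAT (p = 0.183) and -0.51 in aorta (p = 0.00603). A drift along this order stays open in aorta, and the other 3 tissues neither show nor exclude one. Numbers also run group by group within each tissue, so between groups a drift and a group effect cannot be told apart. In aorta, mean Ndufa12 was 93.6, 71.7, 57.2, 41.3 and 39.7 CPM scaled by TMM in the order of the numbers (chow, HFD control, semaglutide, running, both).

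Of 124 groups of 4 to 10 libraries tested over 11 measures, 12 had 1 library far from the others, where chance gives about 1 in 20. In pgWAT under the combined treatment, animal 82 had a liver RNA share of 7.65% (others 0.011 to 0.593%), animal 80 a matrix score of 7.1 (7.6 to 7.86) and a cell cycle score of 3.93 (2.88 to 3.22) in log2 CPM, and animal 73 a clock score of 4.62 (4.88 to 5.09). Semaglutide animal 40 had a pgWAT matrix score of 9.28 (8 to 8.34). In aorta, HFD animal 33 had a liver RNA share of 1.05% (0.0108 to 0.207%) and semaglutide animal 39 one of 0.157% (0.00384 to 0.0569%). HFD animal 27, whose aorta sample had excess fat removed, had 99.6 CPM of Ndufa12 scaled to the library total alone (63.3 to 76.1) and an oxidative phosphorylation score of 7.92 (6.73 to 7.24). Semaglutide animal 48 had an aorta adipocyte score of 8.5 (7.21 to 7.78) and a clock score of 5.37 (4.82 to 5.04), and chow animal 6 a liver adipocyte score of 5.54 (2.26 to 3.56).

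For 49 gene effects called in opposite directions in a pair of tissues the difference was taken in log2 CPM, with permutation tests adjusted over the 49. The genes were picked for opposite calls, so a small p restates the choice and adds no evidence. Most are hepatocyte genes whose fall in muscle liver RNA could set. Fabp3 for the diet did not pass (1.837 higher in muscle than in liver, adjusted p = 0.0528, 23 animals). Values of some genes that the text names follow. The diet effect on Ech1 was 0.839 higher in muscle than in liver (adjusted p = 9.19e-05, 23 animals), and that on Fabp5 was 1.052 higher in pgWAT than in aorta (adjusted p = 6.68e-05, 20 animals). The effect on Alb was 3.368 higher in liver than in muscle with semaglutide (adjusted p = 0.000228, 30 animals) and 3.819 higher with both treatments (adjusted p = 0.000106, 29 animals). With semaglutide the effect was also higher in liver than in muscle by 3.293 for Fgb (adjusted p = 9.19e-05) and 1.242 for Gcgr (adjusted p = 0.00138). That of both treatments on Rgs2 was 0.991 higher in muscle than in liver (adjusted p = 0.000831, 29 animals). For both treatments the effect was also higher in liver than in muscle by 3.677 for Fgb (adjusted p = 0.000101), 3.722 for Fgg (adjusted p = 4.45e-05, from the smallest p that the permutations can give) and 1.166 for Gcgr (adjusted p = 0.00324), with 29 animals each.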

How the results depend on the processing

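Alternatives chosen after the data were seen are the liver RNA share, duct score and Ndufa12 with Gpx1 covariates, the fits without genes that liver RNA could set, and those without or merging single libraries. Of 306 values of main results under alternatives, 216 kept to their bound (1.5 times for counts, 1 SD of the splits for shares) and 90 did not. Of 1621 values of named genes under alternatives, 1376 kept direction and side of the threshold, 208 lost the call, 15 gained it and 15 turned direction, while 7 uncalled values changed sign. Of 153 named values called, 74 were called under every alternative and 146 kept direction under every one. Where a count changed, the cause was not tested, except that fits with fewer genes or libraries and those for which a single library is named show it by construction. Counts of 0 below are from edgeR.

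DESeq2 gave 198 muscle genes for both treatments against semaglutide, 10 against running and 116 for the interaction. In pgWAT it gave 1674 for the diet, 108 for semaglutide, 5 for running, 10 for both against semaglutide and 2 for the interaction, and in aorta 208 for the diet, 47 for both and 68 for both against running. Its size factors gave 3 muscle genes for both against semaglutide. Without a low-count filter muscle had 22 for the diet, 2 for both against semaglutide and 1 against running, pgWAT 104 for the diet, 1051 for both against running and 0 for the interaction, and aorta 9 for the diet, 3 for both and 10 for both against running. Fits of only the groups compared gave 59 in liver for both against semaglutide, and in muscle 64 for semaglutide, 28 for running, 112 for both, 0 for both against semaglutide (1780 at an unadjusted p under 0.05) and 30 for the interaction. They gave 967 in pgWAT for both against running and 0 for the interaction, and in aorta 0 for the diet (2193 unadjusted), 90 for both and 10 for both against running.

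Without genes that liver RNA could set, muscle had 18 for the diet, 6 for semaglutide, 0 for running (1246 unadjusted), 211 for both, 3 for both against semaglutide and 0 for the interaction (350 unadjusted), and pgWAT 27 for the diet. With the liver RNA share as a covariate muscle had 5, 11, 0 (877 unadjusted), 35, 2 and 0 (629 unadjusted) in that order, pgWAT 2 for the diet and 0 for the interaction, and aorta 0 for both (1265 unadjusted). With the adipocyte score as a covariate muscle had 79 for the diet, and aorta 353 for the diet, 1 for semaglutide and 27 for both. With Ndufa12 and Gpx1 as a covariate liver had 413 for both against semaglutide, aorta 12 for the diet and 29 for both, and pgWAT 0 for the interaction. The duct score as a covariate gave 1324 pgWAT genes for the diet and 0 for the interaction, as did the epididymis score for the interaction. Without the libraries highest in duct markers pgWAT had 54 for both, 20 for both against running and 0 for the interaction, and with animals 70 and 71 counted as 1 it had 916 for both against running and 0 for the interaction. With the latter, the duct covariate and no genes that liver RNA could set, it had 232 for the diet, 1011 for both and 0 for the interaction. Without pgWAT animal 40 or 62 the interaction called 0, and over these alternatives it had 715 to 2810 genes at an unadjusted p under 0.05. Without liver animals 6 and 43 both against semaglutide had 93 genes, and 102 without animal 43 alone. Without muscle HFD animal 24 the diet had 29. Without the 2 aorta samples with excess fat removed the diet had 88, running 1 and both against running 26, and leaving out a chow animal gave 4 to 96 for the diet.

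Of 324 list tests called by camera, 4 were called with an estimated correlation, and fry called 65. Unsplit controls gave shares of diet-changed genes moved back of 81.1, 82.5 and 82.1% in liver, 75.3, 78.6 and 85.7% in pgWAT, 53.1, 30.6 and 34.7% in muscle and 88.7, 96.2 and 92.5% in aorta for semaglutide, running and both. Shared controls alone gave the simulated shares above, with more genes called for the diet in every tissue. Both correlations between tissues of the same animals passed without the 2 animals farthest from the median.

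Genes that turned direction were these. Cyp21a1 in liver with semaglutide was at -2.75 in DESeq2, -2.85 without animals 6 and 43 and -2.84 without 43 (adjusted p 6.42e-07 to 0.0223). For both against semaglutide, Star was at 0.43, 0.42 and 0.43 in the same order (adjusted p 0.361 to 0.84), and Cyp21a1 at 1.14 without 6 and 43 and 1.15 without 43 (0.483 and 0.711). Myh8 in muscle was at 0.061, 0.063 and 0.044 in DESeq2 for semaglutide, running and both. It was at 0.066, 0.067 and 0.049 without HFD animal 24 (adjusted p 0.912 to 0.985 over these). Alb in muscle with semaglutide was at 0.17 with the liver RNA share, of which Alb is itself a gene, as a covariate (0.893).

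Other splits of the libraries into groups of the same sizes were fitted, 25 per comparison with the real one. Only 1 of 25 splits, the real one, called as many genes for these comparisons: in liver for the diet (4502, highest other 0), semaglutide (2729, 3), both (4763, 90), both against semaglutide (201, 5) and against running (2222, 149), in muscle for semaglutide (260, 3), running (234, 1), both (553, 115) and the interaction (61, 5), in pgWAT for the diet (817, 71), both (1924, 214) and both against running (1618, 347), and in aorta for the diet (53, 1) and both against running (16, 1). With 25 splits no smaller share than 1 of 25 is possible, and it was not adjusted over the comparisons. It is thus limited evidence against chance. Such counts may also come from features that go with the groups, such as the liver RNA share in muscle. Chance cannot be excluded for the muscle diet effect (2 of 25 splits, 49 genes, highest other 158, which points to a structure of the muscle libraries), both against semaglutide in muscle (4 of 25, 9 genes, highest other 24), the pgWAT interaction (3 of 25, 1 gene, highest other 25) and both in aorta (2 of 25, 5 genes, highest other 5). The comparisons with 0 calls were met by all 25 splits, with at most 3 genes in another split. No paired analysis was possible because each animal is in 1 group of a tissue. Depth of 7717769 counts or more and 4 to 15 animals limit what can be seen: in simulations 28.4% of 1.5-fold changes were recovered for the aorta diet effect.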

Other observations

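Other liver genes of hormone, glucose and immune functions changed under the combined treatment. The glucagon receptor gene Gcgr rose (0.25 ± 0.06, adjusted p = 0.00173), while the gluconeogenesis genes Pcx (-0.39 ± 0.05, adjusted p = 4.59e-08) and Fbp1 (-0.34 ± 0.07, adjusted p = 0.00014) fell. Of the gluconeogenesis list, 2 of 11 members fell (2 adjusted over the list alone) (camera adjusted p = 0.67 preset, 0.926 estimated, with a median of 0.08, a mean of 0.02 and a test direction down). The fibrinogen genes Fgb (0.57 ± 0.09, adjusted p = 2.28e-06) and Fgg (0.59 ± 0.09, adjusted p = 1.36e-06) rose, and of the acute phase list, 5 of 19 members rose and 2 fell (5 and 4 adjusted over the list alone) (camera adjusted p = 0.88 preset, 0.983 estimated, with a median of -0.14, a mean of -0.10 and a test direction up). The B-cell genes Cd19 (0.88 ± 0.24, adjusted p = 0.00293) and Cd79b (0.90 ± 0.25, adjusted p = 0.00357) rose, largely through combined-treatment animal 79, at 18 CPM of Cd19 where the others had at most 6.06. Without it Cd19 was at 0.50 and still passed, and Cd79b was at 0.51 (adjusted p = 0.0515). Of the lymphocyte list, 4 of 18 members rose (3 adjusted over the list alone, camera adjusted p = 0.108 preset, 0.745 estimated), and 1 without animal 79.

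Tph2, which makes serotonin in neurons, and other genes chosen after their values were seen were lower in muscle and in part elsewhere, and the tests of fat cells on them were also chosen after. Tph2 fell under the combined treatment in muscle (-2.87 ± 0.53, adjusted p = 0.000101), pgWAT (-2.52 ± 0.56, adjusted p = 0.0042) and aorta, where chance cannot be excluded for the count of calls. The integrin gene Itgad fell in muscle (-1.86 ± 0.33, adjusted p = 3.21e-05) and pgWAT (-2.65 ± 0.51, adjusted p = 0.00184), Crtac1 (-1.48 ± 0.38, adjusted p = 0.0111) and 1700047G03Rik (-2.40 ± 0.57, adjusted p = 0.00476) in muscle as in aorta, and Lipf (-3.25 ± 0.65, adjusted p = 0.000349) and Slc5a7 (-2.40 ± 0.58, adjusted p = 0.00651) in muscle. With semaglutide alone Tph2 (-1.96), Itgad (-1.66) and Lipf (-3.02) also fell in muscle (adjusted p = 0.00677, 0.000149 and 0.000421; Tph2 missed the threshold at -2.30, adjusted p = 0.0772, with the liver RNA share as a covariate and at -1.97, adjusted p = 0.0706, without the genes that liver RNA could set), and Crtac1, Slc5a7 and 1700047G03Rik did not pass (adjusted p = 0.327, 0.123 and 0.179). Srpx2, lower in aorta, also fell in liver (-0.56 ± 0.12, adjusted p = 0.000451). In pgWAT, Crtac1 (0.001, adjusted p = 0.999), Srpx2 (-0.26, adjusted p = 0.37), Lipf (-1.03, adjusted p = 0.226), Slc5a7 (-1.15, adjusted p = 0.0958) and 1700047G03Rik (-0.93, adjusted p = 0.0636) did not pass, nor did Itgad in aorta (-0.11, adjusted p = 0.897). Without the libraries highest in duct markers Lipf and Slc5a7 did pass in pgWAT (-2.80 and -2.50, adjusted p = 0.0452 and 0.0249).

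Whether a lower share of fat-cell RNA in muscle libraries caused the lower Tph2, Itgad, Crtac1, Lipf, Slc5a7 and 1700047G03Rik there stays open. The fit with the adipocyte score below cannot decide it, since a mean of marker genes measures fat-cell content imperfectly. Over 15 adipocyte markers the log2 fold change in muscle had a median of -0.29 (10th to 90th percentile -1.08 to 0.41), against -3.25 to -1.48 for the 6 genes. The 6 genes were chosen after their falls were seen, so this contrast follows in part from the choice. With the adipocyte score as a covariate 6 of 6 passed, at a median of 0.78 of their log2 fold change (0.7 to 0.79). Fat cells as the source of these transcripts, with a change in the cells, stay open. In HFD controls the markers had a median ratio of muscle to pgWAT of 4.05% (1.58 to 11.4%), and 4 of 6 genes lay within 2-fold of it (1.23 to 4.94%). In aorta 0 of 6 lay within 2-fold of the marker median of 41.6% (1.58 to 13.3%). Crtac1 did not show such a change in pgWAT, and fat cells of muscle were not measured apart.

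The fitted log2 fold changes of 17 clock genes under the combined treatment were correlated between liver and muscle (r = 0.9, genes not being independent replicates, and r = 0.9 with semaglutide and 0.75 with running alone), as 1 common shift of the clock may give, although 5 of 17 passed in liver and 3 in muscle. Fat did not follow (r = -0.17 between liver and pgWAT and -0.05 between muscle and pgWAT, with a negative mean product of the changes and permutation p = 0.999 and 1 for the same direction), while aorta had r = 0.69 with liver and 0.73 with muscle (adjusted p = 0.176 and 0.0976). When treatment labels of animals were permuted jointly over both tissues, the r of mean log2 CPM differences was 0.87 against a median of 0.69, and the mean product of the changes gave permutation p = 0.0109, adjusted p = 0.0976 over 18 relations, none of which passed. The hour of dissection is not in the labels, so a shift of the clock and a difference in sampling time cannot be told apart.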
